A study of Homo sapiens with 23 samples.

How the data were processed

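RNA-seq libraries were made from 1 µg of total RNA of HCT116 cells after poly(A) selection, per the labels' protocols. The series has 23 samples, of which the 8 RNA-seq libraries were analysed and the 15 ChIP-seq samples (MLL4, tagged BAP1, H3K4me1 and inputs) were not analysed here. Groups and replicate numbers were taken from the sample titles: WT, MLL4 KO, control and BAP1 KO, with 2 libraries in each.

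Each library has a deposited table with a read count and an RPKM value for every RefSeq transcript, per the file headers. The counts are whole numbers that the authors did not normalize, and the deposited RPKM values are reads scaled to transcript length and library size. The submitters' processing notes name the build hg38 and the tools bcl2fastq, Bowtie2, STAR and SICER 1.1 without saying which was used for which data. The counting tool, the strand setting and the annotation version are not given in the sources used here. Isoforms of a gene carried nearly the same count, so a read in a shared exon stands in the row of each isoform, and adding transcript rows counts such reads repeatedly. Dividing count by RPKM gave, within 4.2e-07 of a whole base, a transcript length times 1 constant per library, from which the reads behind the RPKM values were computed (31.6 to 54.8 M, 1e6 reads). No RPKM value entered a test. Without strand, reads of overlapping antisense genes cannot be told apart, and readthrough genes share reads with the genes they span.

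The tables held 88819 rows and 76501 distinct transcript identifiers. Identifiers were matched to gene symbols through the RefSeq gene table of the assembly GRCh38.p14, the assembly that hg38 names, and 605 rows with no symbol (0.23% to 0.252% of the summed counts per library) were left out. For each of 28105 genes the transcript row with the highest mean count over the 8 libraries stood for the gene, which gave 24.8 to 42.2 M counts per library. Gene positions come from the same table.

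Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (16831 genes), libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 8 libraries with robust empirical Bayes. The contrasts were MLL4 KO against WT, BAP1 KO against control, the difference of these effects, and control against WT, all two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Standard errors were computed as the log2 fold change over the square root of its F statistic. Levels are TMM-scaled CPM with the SD over 2 libraries. A gene with no read in a group was given a fold against a floor of 3 counts per library, which covers counting error only.

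A set of 30 gene lists was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation, under which no list passed in either comparison. Counts of list members were made over all tested genes and adjusted over the list alone. The overlap of the knockouts was set against independent lists and tested with Fisher's exact test in SciPy 1.17.1. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule takes the targeted genes and, per knockout, the 12 largest changes in each direction. The latter are genes past the threshold with a mean of at least 5 CPM in the higher group and libraries that do not overlap. It also takes the 10 genes in each direction with the smallest p in both knockouts. A further 5 per direction are taken for the difference and for control against WT. From each list that passed it takes 4 members plus up to 2 that moved the other way. The text names only part of this set. Among those left out, ADGRF1 lost its BAP1 KO call in 9 of 21 alternatives and NR2F1 its MLL4 KO call in 10 of 22. SYTL5, IQGAP2, C1QL1 and GALNT5, also left out, lost their BAP1 KO call in none. Unnamed, antisense and small RNA genes were passed over.

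On simulated counts with known changes (MLL4 KO against WT, 16457 genes), the model recovered 7.5% of genes changed 1.5-fold, 74.6% of genes changed 2-fold and 100% of genes changed 4-fold, and 10 of 132 calls were false. In the same simulation BAP1 KO against control held no change and edgeR made 0 calls. Few genes were changed in the simulation, which made 132 calls for MLL4 KO against 3219 in the data. Its cutoff on unadjusted p was therefore stricter, so these shares are not the recovery in the data.

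The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts (1 CPM in 4 libraries), a fit on the 4 libraries of each comparison, no robust step, the legacy dispersion, a test against a 1.5-fold change, the replicate number as a block and leaving out each library. The sum of transcript rows, the longest transcript row and a crossed block were added after seeing the data.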

Results

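Gene expression was measured by RNA-seq of polyadenylated RNA in HCT116, a human colorectal cancer cell line, in 8 libraries that fall into 4 groups of 2. WT cells were set against cells labelled MLL4 knockout, and cells labelled control, whose genotype is also given as WT, were set against cells labelled BAP1 knockout. MLL4, encoded by KMT2D, is a histone methyltransferase that places the H3K4me1 mark at enhancers, and BAP1 is a nuclear deubiquitinase that removes ubiquitin from histone H2A. The series asks which genes depend on each protein and which depend on both, and it also holds 15 ChIP-seq samples that were not analysed here. Reads behind the deposited RPKM values ranged from 31.6 to 54.8 M per library, and counts summed over genes from 24.8 to 42.2 M (M, 1e6 reads). The labels do not say whether replicates came from separate cultures or clones, so every p-value measures only the spread between these libraries. The deposited tables are named with differing numbers for replicates of WT, MLL4 KO and BAP1 KO, which may be clone numbers. The names for control and BAP1 KO also carry osTir1, a plant receptor used to degrade tagged proteins, and those for WT and MLL4 KO do not, so control may be an engineered line, which its labels do not state.

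Replicates correlated across genes at r = 0.976 in WT, 0.983 in MLL4 KO, 0.992 in control and 0.985 in BAP1 KO on log2 CPM (counts scaled to library size, per 1e6), with genes not being independent replicates. WT replicate 1 was nearly as close to MLL4 KO replicate 1 (r = 0.974) as to WT replicate 2. As a check for a library deposited repeatedly, replicate counts were set against sampling noise, and the chi-square per gene (47.28 in WT, 50.92 in MLL4 KO, 6.48 in control, 24.11 in BAP1 KO) showed none. The first principal component held 40.4% of the variance and separated the WT and MLL4 KO libraries from the control and BAP1 KO libraries. WT replicate 2 lay farthest out on it, at 87.7 against 50.6 for WT replicate 1. The 10 genes with the most reads took 10.71% and 9.44% of the counts in the control libraries, against 5.11% to 7.33% in the other 6 libraries.

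**Figure D1:**
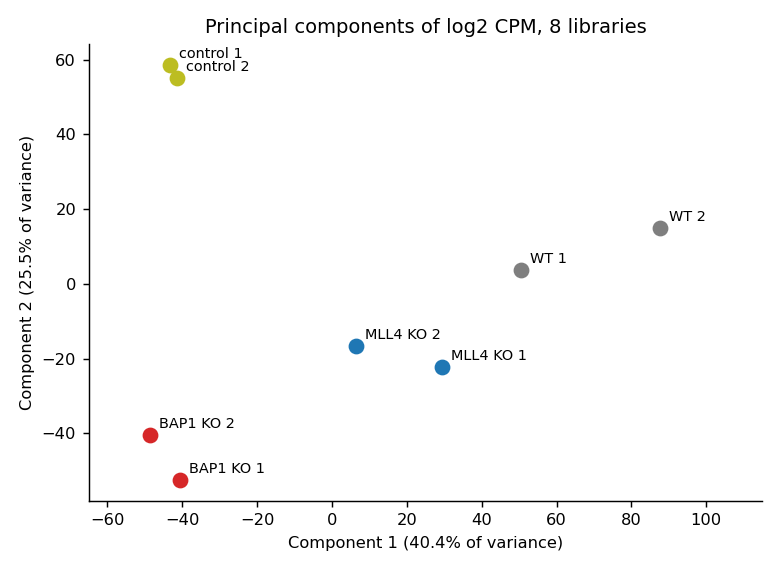
First and second principal components of log2 CPM for the 8 libraries, each point being 1 library coloured by group, with 40.4% and 25.5% of the variance on the axes. WT replicate 2 sits at 87.7 on the first axis, and the BAP1 KO and control libraries are parted along the second.

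The messenger RNA of neither targeted gene was lower in its own knockout. KMT2D (chromosome 12, 49018978 to 49060794, hg38, counted on transcript NM_003482) stood at 309 and 371 CPM in the WT libraries and at 280 and 406 CPM in the libraries labelled MLL4 KO, a log2 fold change of 0.01 ± 0.18 (SE, n = 2 against 2, adjusted p = 0.97). It was 239 and 259 CPM in control and 267 and 228 CPM in BAP1 KO. BAP1 (chromosome 3, 52401008 to 52410008, hg38, counted on transcript NM_004656) stood at 56.7 and 62.1 CPM in control and at 67.4 and 57.4 CPM in the libraries labelled BAP1 KO, a log2 fold change of 0.07 ± 0.13 (SE, n = 2 against 2, adjusted p = 0.746). It was 77.9 and 92.1 CPM in WT and 73.2 and 69.8 CPM in MLL4 KO. How the knockouts were made is not given in the sources used here, and a frameshift or a small deletion can leave the transcript and its reads in place, so these levels do not check the labels. Every direction below rests on the labels alone.

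**Figure D2:**
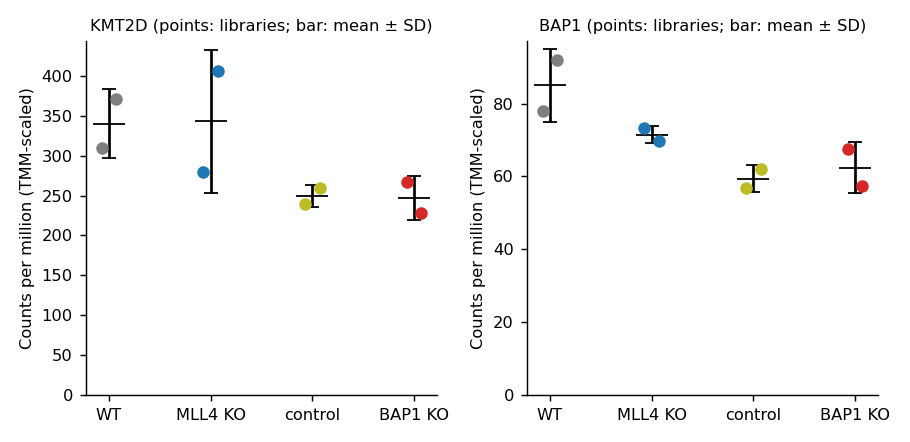
KMT2D and BAP1 in TMM-scaled CPM by group, with a point for each library and bars for the mean ± SD (n = 2). KMT2D means were 340 in WT and 343 in MLL4 KO, and BAP1 means were 59.4 in control and 62.4 in BAP1 KO.

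In the libraries labelled MLL4 KO, ADGRG6, EPHA2, EGR3, SHC2 and DDIT3 rose and SLC1A3, MGLL and MEF2C fell. ADGRG6, an adhesion G protein-coupled receptor, rose from 68.1 ± 12.7 to 316 ± 45.2 CPM (SD, n = 2), a log2 fold change of 2.21 ± 0.17 (SE, adjusted p = 0.000709). EPHA2, an ephrin receptor tyrosine kinase, rose by 1.42 ± 0.14 (adjusted p = 0.00248), the immediate early transcription factor EGR3 by 3.17 ± 0.36 (adjusted p = 0.00318) and the signalling adaptor SHC2 by 2.99 ± 0.32 (adjusted p = 0.00318). DDIT3, the stress transcription factor CHOP, rose from 14.5 ± 5.72 to 123 ± 45.3 CPM, a log2 fold change of 3.07 ± 0.41 (adjusted p = 0.0101). Downwards, the glutamate transporter gene SLC1A3 went from 22.7 ± 5.45 to 2.25 ± 0.185 CPM and fell by 3.33 ± 0.23 on the log2 scale (adjusted p = 0.000709). The monoacylglycerol lipase gene MGLL fell by 2.9 ± 0.27 (adjusted p = 0.00225) and the transcription factor gene MEF2C fell by 2.49 ± 0.25 (adjusted p = 0.00248).

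Of the other genes with the largest rises, the neural adhesion gene TMEM132B changed by 3.79 ± 0.47 on the log2 scale, the lipoprotein receptor-related gene LRP1B by 4.22 ± 0.63, CNTNAP2 by 3.69 ± 0.75, and CHAC1, an enzyme that degrades glutathione, by 3.47 ± 0.47. LRP1B, CNTNAP2 and CHAC1 had adjusted p = 0.0552, 0.0621 and 0.0698 without WT replicate 2. KRT5, a basal keratin, had the largest fitted change at 5.78 ± 1.31, but its knockout level of 5.72 ± 6.04 CPM had an SD above its mean and its adjusted p was 0.0962 and 0.184 without WT replicate 1 or 2 and 0.0561 and 0.0568 without control replicate 1 or 2. GDF15, a stress-induced cytokine, rose from 67.7 ± 47.3 to 581 ± 203 CPM, with adjusted p = 0.0932 without MLL4 KO replicate 2, 0.0569 without control replicate 1 and 0.0566 without control replicate 2. TNFRSF6B, a soluble decoy receptor, shares its locus with a readthrough transcript, so its change of 3.66 ± 0.64 is uncertain as to gene, with adjusted p = 0.0851 without MLL4 KO replicate 2 and 0.0536 and 0.0537 without control replicate 1 or 2. Among the largest falls were the axon guidance gene NAV3, which fell by 3.88 ± 0.49, the WNT regulator DACT1, which fell by 2.5 ± 0.32, and THBS1, the matrix protein thrombospondin 1, which fell by 2.42 ± 0.38. HSPA1A and HSPA1B, heat shock chaperone genes with near-identical sequences whose reads cannot be assigned with certainty, each fell by 2.08 ± 0.41, with WT SDs of 535 and 676 CPM. Without any 1 of the MLL4 KO or control libraries their adjusted p lay between 0.0501 and 0.124.

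In all, 3219 of 16831 tested genes passed an adjusted p of 0.05 in MLL4 KO against WT, 1536 higher and 1683 lower, and 712 and 291 of them differed by at least 2-fold. With upper-quartile scaling the split was 1886 higher and 1211 lower, since the median of all genes moved to 0.088 on the log2 scale. This count depended on which libraries shared the fit: it was 60 (46 higher, 14 lower) with only the 4 libraries of this comparison, 677 without WT replicate 2, 5300 without WT replicate 1, 492 without MLL4 KO replicate 2, and 1072 and 1106 without control replicate 1 or 2. The groups differed in spread: the median log2 difference between replicates was 0.287 in WT and 0.22 in MLL4 KO, against 0.095 in control and 0.188 in BAP1 KO. The shared fit pools the spread of all groups, so the MLL4 KO p-values rest in part on the closer control and BAP1 KO replicates. Of the 99 genes past the threshold that the rule takes for this comparison, 24 kept their call in the fit on 4 libraries. Among them were ADGRG6, EPHA2, EGR3, SHC2, DDIT3, SLC1A3, MGLL and MEF2C. TMEM132B, NAV3, DACT1 and THBS1, named above, lost their call in the fit on 4 libraries. So did EDEM1, CDKN1B, CDKN2B, ID3, DUSP4, SPRED2, HLA-B, HLA-F, PSMB9, IRF7, HMGCS1, STMN3 and CYP4F11, named below.

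In the libraries labelled MLL4 KO, the ATF4 list passed upwards and the cell cycle list downwards. Of 36 measured targets of ATF4 and the unfolded protein response, which answer amino acid shortage and misfolded protein, 19 rose, none fell and 17 did not pass, with a median log2 change of 0.86 (adjusted p = 4.36e-12 for the list). Besides DDIT3, EDEM1, which clears misfolded proteins from the endoplasmic reticulum, rose by 0.89 ± 0.15 (adjusted p = 0.0104). The rise was uneven between libraries: the list's median level was 5.96 and 6.05 log2(CPM + 1) in WT, 6.67 in MLL4 KO replicate 1 and 7.64 in MLL4 KO replicate 2. Of 63 cell cycle and E2F target genes, 37 fell, none rose and 26 did not pass, with a median of -0.63 (adjusted p = 1.9e-16). The kinetochore gene CENPF changed by -1.03 ± 0.17 and the E2F family gene E2F8 by -0.99 ± 0.17, with adjusted p = 0.0575 and 0.0559 without MLL4 KO replicate 2. With p adjusted over the list alone, 24 of the ATF4 genes (23 higher, 1 lower) and 52 of the cell cycle genes (all lower) passed. Both lists were at adjusted p = 0.52 with an estimated correlation between genes.

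The lists of cell cycle inhibitors and p53 targets passed upwards. These lists share CDKN1A and GDF15, and SESN2 is in both the p53 and the ATF4 list. Of 21 measured cell cycle inhibitors and senescence-associated genes, 8 rose and 2 fell (median 0.43, adjusted p = 0.00658). CDKN1B, which encodes the inhibitor p27, rose by 1.16 ± 0.15 (adjusted p = 0.0054) and CDKN2B, which encodes p15, by 1.35 ± 0.22 (adjusted p = 0.00943), while CDKN1A, which encodes p21, changed by 1.26 ± 0.26 and had adjusted p = 0.0996 without MLL4 KO replicate 2. The pair that fell were RBL1, a pocket protein, with adjusted p from 0.0538 to 0.209 without any 1 library but MLL4 KO replicate 1, and LMNB1, which encodes lamin B1, with 0.0717 to 0.226 without any 1 library but WT replicate 1. Of 37 p53 target genes, 13 rose and 2 fell (median 0.46, adjusted p = 9.62e-06). Among those that rose were SESN2, a sensor of amino acid stress, at 2.18 ± 0.29 and GADD45A at 1.72 ± 0.28, with adjusted p = 0.0584 and 0.0852 without WT replicate 2. The p53 targets that fell were TIGAR, with adjusted p from 0.0555 to 0.109 without WT replicate 2, MLL4 KO replicate 2 or either control library, and AEN, with 0.0506 to 0.126 without those or MLL4 KO replicate 1. Adjusted over the list alone, 11 inhibitor genes (9 higher, 2 lower) and 16 p53 targets (14 higher, 2 lower) passed, and both lists were at adjusted p = 0.52 with an estimated correlation.

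TGF-beta, MAPK, MHC and interferon lists passed upwards. The MHC and interferon lists share TAP1, PSMB8 and PSMB9, so they are not fully separate evidence. Of 26 TGF-beta and BMP response genes 9 rose and none fell (median 0.71, adjusted p = 0.000241), led by ID3, an inhibitor of helix-loop-helix transcription factors, which rose from 68.2 ± 28.4 to 270 ± 65.1 CPM. Of 40 MAPK feedback and immediate early genes 15 rose and 2 fell (median 0.35, adjusted p = 0.00103). The MAPK phosphatase gene DUSP4 rose by 1.17 ± 0.16 and SPRED2, a feedback inhibitor of RAS signalling, by 0.8 ± 0.11, and the genes that fell were DUSP7 and MYC. Without WT replicate 2, MLL4 KO replicate 2 or either control library, adjusted p was 0.0555 to 0.114 for DUSP7 (0.0682 without MLL4 KO replicate 1) and 0.0674 to 0.161 for MYC. Of 27 genes of MHC antigen presentation 15 rose and none fell (median 0.68, adjusted p = 1.59e-06), with HLA-B at 1.19 ± 0.16, HLA-F at 1.24 ± 0.14 and the immunoproteasome subunit gene PSMB9 at 1.93 ± 0.31. All the MHC genes that rose but B2M lie on chromosome 6, where PSMB9 is in a run of 29 genes with a median of 0.57 and HLA-F in a run of 8 genes with a median of 0.79. Reads of HLA genes can be shared between near-identical paralogs, so single HLA values are uncertain. Of 48 interferon response genes 11 rose and 2 fell, SAMD9 and IFIT5 (median 0.35, adjusted p = 0.00189), with the interferon regulatory factor gene IRF7 at 1.51 ± 0.24. SAMD9 had adjusted p = 0.0687 without MLL4 KO replicate 2, and IFIT5 had 0.0533 to 0.0758 without that library, WT replicate 2 or either control library. The median levels of WT and MLL4 KO libraries overlapped for the MHC list (3.57 and 3.71 log2(CPM + 1) in WT, 3.89 and 3.55 in MLL4 KO) and the MAPK list (6.33 and 5.61 in WT, 6.11 and 6.35 in MLL4 KO), and lay close in 1 library of each group for the TGF-beta list (4.7 and 4.32 in WT, 4.75 and 5.28 in MLL4 KO). With p adjusted over the list alone, 11 TGF-beta genes (all higher), 19 MAPK genes (15 higher, 4 lower), 19 MHC genes (17 higher, 2 lower) and 13 interferon genes (11 higher, 2 lower) passed. Each of the 4 lists was at adjusted p = 0.52 with an estimated correlation.

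Further lists passed in this comparison. Of 27 cholesterol synthesis and uptake genes 10 fell and none rose (median -0.42, adjusted p = 0.000103), among them HMGCS1, a synthase at the start of the pathway, which fell by 1.33 ± 0.17. Of 49 developmental transcription factor genes outside the HOX clusters 10 rose and none fell (median 0.35, adjusted p = 0.00627), among them FOXC1 at 1.65 ± 0.27, with adjusted p = 0.056 without MLL4 KO replicate 2. Of 20 neuronal and synaptic genes 5 rose (list adjusted p = 0.00292): STMN3, a regulator of microtubules, at 1.04 ± 0.12, NCAM1, CNTNAP2, GRIK2 and CELSR3. Without WT replicate 2 adjusted p was 0.0621 for CNTNAP2, 0.0677 for GRIK2 and 0.0959 for CELSR3 (0.0949 without MLL4 KO replicate 2), and the list's median levels overlapped (3.05 and 2.89 log2(CPM + 1) in WT, 3 and 3.51 in MLL4 KO). Of 77 cytosolic ribosomal protein genes 4 rose, RPL13A, RPL3, RPL28 and RPS27 (median 0.19, adjusted p = 0.00402), and of 55 nuclear-encoded oxidative phosphorylation genes 6 fell (median -0.14, adjusted p = 0.0101). Each of the 4 ribosomal genes lost its call, at adjusted p from 0.0637 to 0.21, without WT replicate 2, MLL4 KO replicate 2 or either control library, as did RPL28 (0.0567) and RPS27 (0.0663) without WT replicate 1 and RPS27 (0.0596) without MLL4 KO replicate 1. Adjusted over the list alone, 16 cholesterol genes (14 lower, 2 higher), 10 developmental genes, 11 neuronal genes (10 higher, 1 lower), 0 ribosomal genes and 4 oxidative phosphorylation genes passed by edgeR. Without WT replicate 1 the cholesterol and ribosomal lists were at adjusted p = 0.163 and 0.228, and without MLL4 KO replicate 2 the oxidative phosphorylation list was at 0.133. With an estimated correlation, adjusted p = 0.52 for the cholesterol, developmental and neuronal lists, 0.815 for the ribosomal list and 0.693 for the oxidative phosphorylation list.

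In the libraries labelled BAP1 KO, PCDH7, LCN2, GDA, SLC1A3 and DPP4 fell and DKK1 and RAB3B rose. PCDH7, a protocadherin, was at 59.7 ± 0.232 CPM in control (SD, n = 2) and had no read in either knockout library, at least 590-fold lower when a floor of 3 counts per library was used. LCN2, an iron-siderophore-binding protein, went from 149 ± 4.25 to 0.334 ± 0.0692 CPM, a log2 fold change of -8.78 ± 0.5 (SE, adjusted p = 4.89e-05). LCN2 was also low in WT, at 0.757 ± 0.849 CPM, so control stood apart for this gene. PCDH7, GDA and SLC1A3 were at 79 ± 4.11, 56.3 ± 4.93 and 22.7 ± 5.45 CPM in WT, and BAP1 KO lay below both WT and control. GDA, guanine deaminase, fell by 5.76 ± 0.29 (adjusted p = 1.07e-05), SLC1A3 fell by 5.4 ± 0.34 (adjusted p = 2.96e-05) and DPP4, a brush border peptidase, fell by 5.46 ± 0.62 (adjusted p = 0.000633). Upwards, the WNT antagonist gene DKK1 went from 19.4 ± 1.2 to 530 ± 112 CPM, a log2 fold change of 4.78 ± 0.6 (adjusted p = 0.00376), and RAB3B, a small GTPase of vesicle secretion, from 124 ± 6.08 to 1720 ± 251 CPM, a change of 3.79 ± 0.38 (adjusted p = 0.000821).

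The neurotrophin receptor gene NGFR rose by 4.12 ± 0.21 (adjusted p = 1.07e-05) and SLC16A6, of the monocarboxylate transporter family, by 3.88 ± 0.17 (adjusted p = 6.49e-06). TNFSF4, the OX40 ligand, rose by 4.85 ± 0.51, the chemoattractant receptor gene GPR15 by 5.2 ± 0.45, the cadherin-related gene CDHR3 by 3.69 ± 0.3 and the long noncoding RNA LNCAROD by 5.44 ± 0.57. The genes with the largest falls also included the protease inhibitor gene SLPI, which fell by 5.48 ± 0.49, the myoglobin gene MB, which fell by 6.27 ± 0.47, PROM2, which fell by 5.85 ± 0.59, and the hexokinase family gene HKDC1, which fell by 5.36 ± 0.58. TFPI, the tissue factor pathway inhibitor, went from 24.6 ± 1.7 CPM to 2 counts in the knockout libraries together.

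In all, 3778 of 16831 tested genes passed in BAP1 KO against control, 2035 higher and 1743 lower, and 843 and 767 of them differed by at least 2-fold. The count was 6659 with only the 4 libraries of this comparison, and it was 1154 and 1090 without control replicate 1 or 2 and 1360 and 2441 without BAP1 KO replicate 1 or 2. All 83 genes past the threshold that the rule takes for this comparison kept their call in the fit on 4 libraries.

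In the libraries labelled BAP1 KO, the cell cycle list passed upwards and the epithelial junction list downwards. Of 63 cell cycle and E2F target genes 57 rose, none fell and 6 did not pass, with a median log2 change of 1.07 (adjusted p = 1.55e-35 for the list). FOXM1, a transcription factor of the G2 and M phases, rose from 18.9 ± 0.387 to 55.8 ± 0.399 CPM, and the mitotic kinesin gene KIF20A rose by 1.95 ± 0.17. The control libraries started low: the list's median level was 4.43 and 4.47 log2(CPM + 1) in control, 5.68 and 5.37 in BAP1 KO, 6.76 and 6.84 in WT and 6.33 and 6.19 in MLL4 KO. Of 44 epithelial junction and polarity genes 20 fell and 1 rose, with a median of -0.97 (adjusted p = 2.33e-14). The junction list's median level was highest in control, at 6.67 and 6.7 log2(CPM + 1), with 5.22 and 5.82 in BAP1 KO. It was 6.2 and 5.84 in WT and 5.74 and 5.72 in MLL4 KO. GRHL2, a transcription factor of epithelial identity, went from 42.5 ± 1.4 to 1.9 ± 0.886 CPM, a change of -4.5 ± 0.25, the desmosomal cadherin gene DSC2 fell by 2.77 ± 0.27 and CGN, which encodes the tight junction protein cingulin, fell by 2.21 ± 0.26. The gene that rose was CLDN2, which encodes a pore-forming claudin and had adjusted p = 0.182 and 0.148 without control replicate 1 or 2 and 0.287 without BAP1 KO replicate 1. With p adjusted over the list alone, 59 cell cycle genes (all higher) and 29 junction genes (28 lower, 1 higher) passed, and both lists were at adjusted p = 0.335 with an estimated correlation.

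The interferon list passed upwards, and the NF-kB and mesenchymal lists passed downwards with members going both ways. Of 48 interferon response genes 22 rose and 1 fell (median 0.8, adjusted p = 3.1e-09), with the antiviral gene OAS3 going from 36.9 ± 2.71 to 182 ± 19.6 CPM and IFI6, an interferon-induced mitochondrial protein, rising by 3.13 ± 0.29. IFI16, a DNA sensor, was the gene that fell, at least 6.14-fold, to no read in either knockout library, with adjusted p = 0.054 without control replicate 1 and 0.0649 without BAP1 KO replicate 1. Of 29 NF-kB and inflammatory cytokine genes 12 fell and 1 rose (median -0.31, adjusted p = 0.000676). The gene that rose, IL11, had adjusted p = 0.0507 and 0.104 without control replicate 1 or 2, and besides LCN2 the apoptosis inhibitor gene BIRC3 fell by 2.15 ± 0.24 and the chemokine gene CXCL2 fell by 3.92 ± 0.55. The NF-kB list stood at 3.9 and 3.82 log2(CPM + 1) in control, 3.09 and 3.47 in BAP1 KO and 2.53 and 2.61 in WT. Of 41 mesenchymal and EMT genes 12 fell and 4 rose (median -0.42, adjusted p = 0.000676). Those that fell were led by CAV1 and CAV2, which encode caveolins and fell by 4.28 ± 0.22 and fell by 3.95 ± 0.2, and LAMA3, a basement membrane laminin of epithelia, which fell by 4.82 ± 0.34. ZEB1, a transcription factor that represses epithelial genes, rose by 2.13 ± 0.27, while VIM, which encodes vimentin, changed by 3.56 ± 0.65 and had adjusted p = 0.0631 and 0.0788 without control replicate 1 or 2. Adjusted over the list alone, 26 interferon genes (24 higher, 2 lower), 13 NF-kB genes (12 lower, 1 higher) and 18 mesenchymal genes (14 lower, 4 higher) passed. With an estimated correlation each of the 3 lists was at adjusted p = 0.335.

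The ribosomal and ATF4 lists passed downwards and the cholesterol list upwards. Of 77 cytosolic ribosomal protein genes 31 fell and none rose (median -0.38, adjusted p = 6e-08), and of 36 targets of ATF4 and the unfolded protein response 7 fell and none rose (median -0.6, adjusted p = 1.64e-05). HSPA5, the main chaperone of the endoplasmic reticulum, fell by 1.3 ± 0.22, from 3390 ± 13.8 to 1380 ± 67.1 CPM. The ATF4 list stood at 7.74 and 7.81 log2(CPM + 1) in control, at 6.6 and 7.28 in BAP1 KO and at 5.96 and 6.05 in WT. The ribosomal list stood at 9.53 and 9.52 in control, at 9.03 and 9.34 in BAP1 KO and at 9.21 and 9.33 in WT. Of 27 cholesterol genes 10 rose and none fell (median 0.43, adjusted p = 0.000973), among them STARD4, a sterol transfer protein, at 1.43 ± 0.17. The cholesterol list was lowest in control, at 5.27 and 5.22, with 5.59 and 5.53 in BAP1 KO and 6.25 and 5.85 in WT. With p adjusted over the list alone, 45 ribosomal, 11 ATF4 and 12 cholesterol genes passed, all in those directions, and each list was at adjusted p = 0.697 with an estimated correlation.

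**Figure D3:**
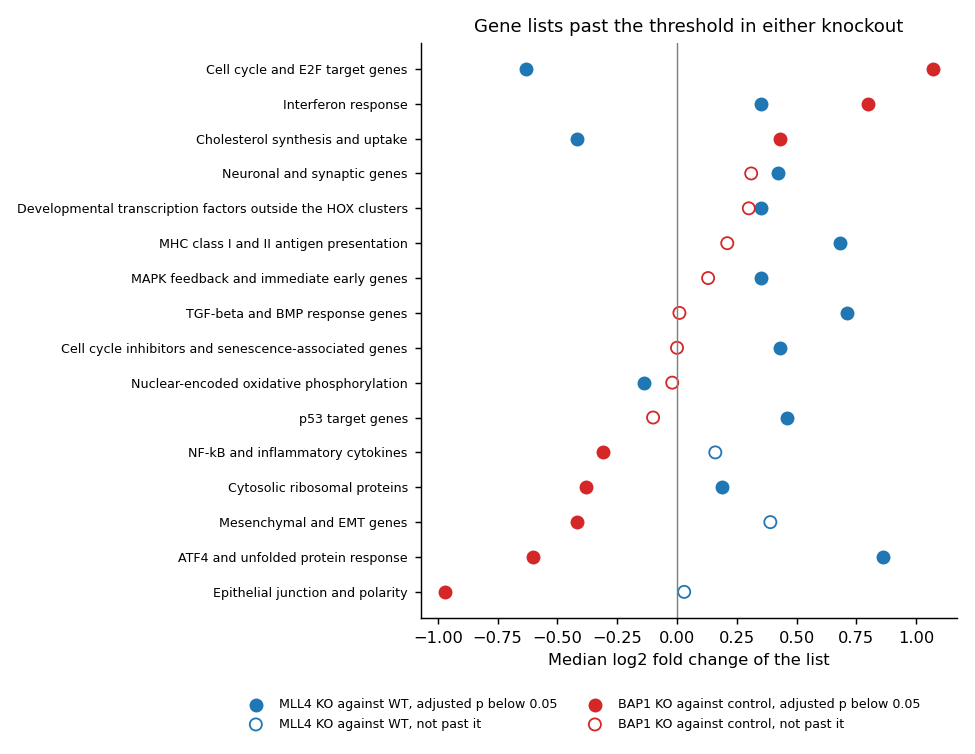
Median log2 fold change of each gene list that passed in at least 1 knockout comparison, filled points being lists at an adjusted p below 0.05 with the preset correlation and open points the others. The cell cycle list was at -0.63 in MLL4 KO and at 1.07 in BAP1 KO, and the interferon list was above 0 in both.

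**Figure D4:**
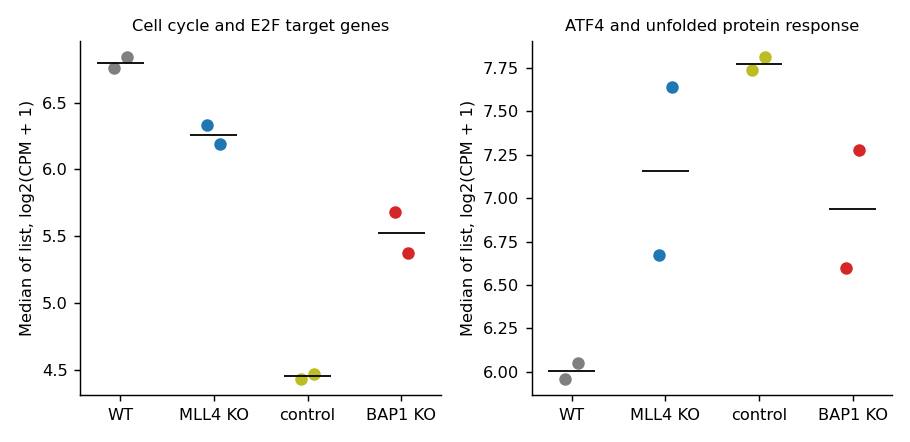
Median level of the cell cycle and the ATF4 list in each library, in log2(CPM + 1), with lines for group means (n = 2). Control libraries were lowest for the cell cycle list, at 4.43 and 4.47, and highest for the ATF4 list, at 7.74 and 7.81.

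A common set of genes changed in both knockouts, each against the WT or control libraries of its own set. NGFR, ADGRG6, the growth factor gene IGF2, the matrix gene MATN2, the LIM-domain gene CRIP2, SAMD5 and APOLD1 rose in both. IGF2 rose by 1.25 ± 0.12 in MLL4 KO and by 1.7 ± 0.12 in BAP1 KO, and CRIP2 by 1.6 ± 0.17 and 2.58 ± 0.18. The readthrough gene INS-IGF2 shares reads with IGF2 and is not separate evidence, though the counts of genes higher in both hold the pair. SLC1A3, MGLL, IRAG1, the phospholipid flippase gene ATP8B1, RNF141 and the keratin gene KRT15 fell in both. ATP8B1 fell by 1.38 ± 0.16 in MLL4 KO and fell by 2.18 ± 0.16 in BAP1 KO, and IRAG1 fell by 1.99 ± 0.2 and fell by 3.82 ± 0.31. In MLL4 KO, IGF2 lies in a run of 43 genes on chromosome 11 with a median log2 change of 0.88, and NGFR in a run of 26 genes on chromosome 17 with a median of 0.62, so these rises sit among shifted neighbours. All of these kept their MLL4 KO call in the fit on 4 libraries.

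Of the 1008 genes that passed in both comparisons, 670 (66.5%) changed the same way. There were 369 higher in both, against 185.7 for independent lists, and 301 lower in both, against 174.3 (Fisher's exact test, one-sided, adjusted p = 3.27e-42 and 5.16e-23 over the 4 directions, with genes not being independent replicates). Genes higher in MLL4 KO and lower in BAP1 KO numbered 125 against 159.1, and genes lower in MLL4 KO and higher in BAP1 KO numbered 213 against 203.5 (adjusted p = 0.999 and 0.317). Opposite changes also exceeded independent lists in some alternatives: without MLL4 KO replicate 1 they numbered 208 against 161.2 and 235 against 180.1 (Fisher's exact p = 4.48e-05 and 5.87e-06). Genes lower in MLL4 KO and higher in BAP1 KO numbered 187 against 130.4 with no filter (exact p = 2.14e-07), 43 against 22.9 with the replicate block (exact p = 4.31e-05), and 29 against 15.9 and 34 against 16.9 without control replicate 1 or 2 (exact p = 0.00136 and 9.45e-05). Across all tested genes the log2 fold changes correlated weakly, at r = 0.107 and rho = 0.122. The count of genes changed the same way was 1341 without WT replicate 1, 271 without WT replicate 2, 170 without MLL4 KO replicate 2, 122 and 119 without control replicate 1 or 2, and 245 and 354 without BAP1 KO replicate 1 or 2. The comparisons share no library, but they share the estimate of the spread.

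**Figure D5:**
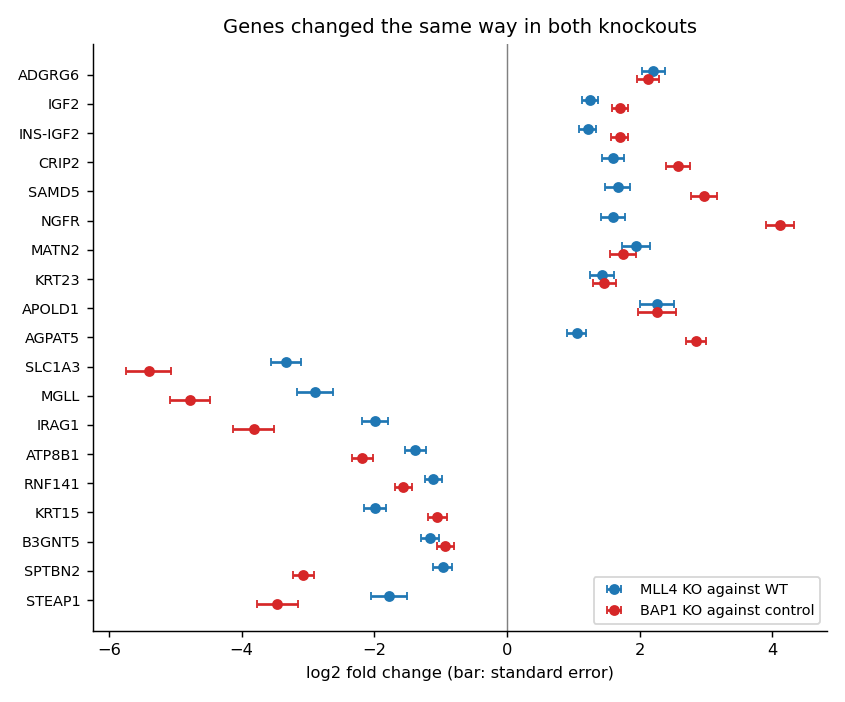
Log2 fold change with standard error (n = 2 against 2) of genes changed the same way in both knockouts, in MLL4 KO against WT and in BAP1 KO against control. ADGRG6 was at 2.21 and 2.13, and SLC1A3 at -3.33 and -5.4.

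The knockout effects also differed for many genes by a test of the difference itself. Differences between the sets, such as those that part control from WT, cancel in this test only if they add on the log scale. GDA fell in BAP1 KO as above, while in MLL4 KO it was at 56.6 ± 15.8 against 56.3 ± 4.93 CPM in WT, and the difference of the effects was 5.77 ± 0.36 (SE, adjusted p = 0.000119). CYP4F11, a fatty acid hydroxylase, rose by 1.13 ± 0.17 in MLL4 KO and fell by 3.97 ± 0.23 in BAP1 KO. It started from like levels, 24 ± 2.49 CPM in WT and 24.4 ± 0.261 in control. ARRDC4, an arrestin-domain gene, rose by 1.87 ± 0.18 and fell by 2.35 ± 0.17, but from unlike levels. It stood at 9.29 ± 2.71 CPM in WT and 33.8 ± 0.0507 in MLL4 KO, against 229 ± 4.42 in control and 44.8 ± 2.27 in BAP1 KO. PKIB, an inhibitor of protein kinase A, went the other way and fell by 1.78 ± 0.25 in MLL4 KO while it rose by 2.98 ± 0.23 in BAP1 KO. HMGB2, a chromatin protein of dividing cells, was at 309 ± 5.69 CPM in MLL4 KO and 334 ± 17 in WT, against 217 ± 24.5 in BAP1 KO and 58 ± 1.25 in control, with a difference of -2.02 ± 0.17 (adjusted p = 0.000601). In all, 2704 genes had effects that differed, 1304 with the MLL4 KO change above the BAP1 KO change and 1400 below it. The count was 4463 without WT replicate 1, 1606 without MLL4 KO replicate 2, 720 and 679 without control replicate 1 or 2, and 885 and 1791 without BAP1 KO replicate 1 or 2.

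More genes differed between control and WT than between either knockout and the WT or control libraries of its set. LCN2 was at 149 ± 4.25 CPM in control and 0.757 ± 0.849 in WT, a log2 difference of 7.72 ± 0.46 (SE, adjusted p = 3.04e-05), and the cytokine gene IL32 was at 58.7 ± 4.01 against 0.671 ± 0.861 CPM, a difference of 6.57 ± 0.98 (adjusted p = 0.00327). NUPR1, a stress-induced transcriptional regulator, was at 8.78 ± 0.0494 CPM in control and had 3 counts in the WT libraries together. PALM3 was lower in control, at 0.401 ± 0.0131 against 10.6 ± 3.38 CPM, a difference of -4.72 ± 0.44 (adjusted p = 0.000101). In BAP1 KO, LCN2 was at 0.334 ± 0.0692 CPM and PALM3 at 9.6 ± 3.35 CPM, both near the WT level. Of the tested genes, 6662 passed (3341 higher and 3321 lower in control), and the count was 3408 and 3280 without control replicate 1 or 2. Neither knockout was tested against the other set.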

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

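The tests of the difference between the gene lists' changes, of WT replicate 2, of the cell cycle levels and of the control libraries against WT, also with separate control libraries, were chosen after the results were seen. The chromosome tests were set out before.

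The effects of the knockouts differed for 2704 genes by edgeR's test of the difference (720 without control replicate 1, 679 without control replicate 2, 885 without BAP1 KO replicate 1, 1791 without BAP1 KO replicate 2, 1606 without MLL4 KO replicate 2 and 4463 without WT replicate 1). Of the genes that passed in both comparisons, 338 changed in opposite directions. Of the 5 gene lists that passed in both knockouts, 4 moved in opposite directions. In each of these 4, both control libraries lay beyond both MLL4 KO libraries on the same side of WT in median level. The cholesterol list, for example, stood at 6.25 and 5.85 log2(CPM + 1) in WT and 5.64 and 5.68 in MLL4 KO. It was 5.27 and 5.22 in control and 5.59 and 5.53 in BAP1 KO. The opposite changes thus start from unlike levels, and the test assumes that set differences add on the log scale. The MLL4 KO change minus the BAP1 KO change had a median of 1.65 on the log2 scale for the ATF4 list (adjusted p = 1.21e-17, or adjusted p = 0.321 with an estimated correlation), -1.76 for the cell cycle list (8.82e-59, or adjusted p = 0.32 with an estimated correlation), -0.82 for the cholesterol list (2.24e-08, or adjusted p = 0.404 with an estimated correlation) and 0.59 for the ribosomal list (9.2e-11, or adjusted p = 0.557 with an estimated correlation).

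Of the genes changed in MLL4 KO against WT, 4.4% lay in runs of 41 neighbouring genes with a shifted median of their own sign. Of all tested genes, 4.2% lay in shifted runs of either sign. The small share argues against long gained or lost chromosome segments as the main source. A segment of few genes would not shift such a median, so short segments were not tested. WT replicate 2 lay farther from the MLL4 KO mean than WT replicate 1 did, with a median log2 distance of 0.358 against 0.24, a ratio of 1.49. That ratio falls just short of the bound set for this library as a source and well above the bound set against it. The share of the count that this library, or loss of MLL4, may account for therefore stays open. Without it 625 of the 3219 genes stayed called, but the loss is not particular to it, as 444 stayed without MLL4 KO replicate 2 and 1072 and 1106 without control replicate 1 or 2. The median size of their log2 changes was 0.77 with all libraries (median SE 0.18), 0.63 without WT replicate 2 (0.18), 0.67 without MLL4 KO replicate 2 (0.2), 0.91 without WT replicate 1 (0.17), 0.88 without MLL4 KO replicate 1 (0.2), and 0.77 and 0.78 without control replicate 1 or 2 (0.2).

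Of the genes changed in BAP1 KO against control, 4.3% lay in such runs, which again argues against long chromosome segments as the main source. Of all tested genes, 3.6% lay in shifted runs of either sign. For 50.9% of the changed genes the BAP1 KO mean was closer to the WT mean than the control mean was, between the bounds set. With the sign of the control difference flipped, 9.5% were. With separate control libraries the share was 51.9% and 48.6% (3.94% and 3.99% with the sign flipped). With control replicate 1 for the BAP1 KO change and control replicate 2 for the difference from WT, 502 of 533 genes that passed in both differed in opposite directions (504 of 534 the other way round), so noise of a shared library is not the source, though both may come from 1 culture. Control enters the BAP1 KO change and the difference from WT with opposite signs. A gene in which only control differs therefore comes out opposite and closer to WT. The shares have no reference value, and flipping the sign does not supply one, so they do not separate the sources. A state of the control cultures, a parent line with osTir1 that differs from WT, and loss of BAP1 could each contribute. They cannot be told apart because control is the only comparison group with that tag.

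The cell cycle list was lower in MLL4 KO by a median level of -0.54 and higher in BAP1 KO by 1.08 on the log2 scale, while control itself stood at -2.35 from WT. Growth state varying between cultures could account for part of this: the largest difference between replicates of a group was 0.31, in BAP1 KO, or 0.57 of the smaller knockout difference. Within each comparison the ratio was 0.26 for MLL4 KO and 0.29 for BAP1 KO. The first value lies between the bounds set, the others lie below them, and whether replicates are separate cultures or clones is not in the labels, so growth state and genotype cannot be told apart for this list.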

How the results depend on the processing

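The sum of transcript rows, the longest transcript row and the crossed block were chosen after seeing the data. With 2 libraries per group, leaving out 1 leaves a lone library that is assumed to vary like the other groups. The simulation used 1 depth, 1 n and far fewer changed genes than were called in the data, so it does not say which limits small changes. Apart from the targeted genes, the genes named by the rule and the lists that passed kept direction in all alternatives tried (other genes among the observations were not run), and 4240 of their values stayed past the threshold while 423 did not. That tally pools all comparisons and alternatives, and the losses were uneven between them. In the fit on 4 libraries 24 of 99 genes kept their call in MLL4 KO and all 83 in BAP1 KO. Against a fold change of 1.5, 41 of 99 kept it in MLL4 KO and 70 of 83 in BAP1 KO. The cause was not tested for the changes given here.

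Replicate numbers did not pair the libraries (correlation of deviations -0.143 in the WT and MLL4 KO set and 0.006 in the other). With the replicate block 792 genes passed in MLL4 KO, 2481 in BAP1 KO, 1352 for the difference, 3072 for control against WT and 185 the same way in both knockouts. With the crossed pairing 3976 passed in MLL4 KO. With own 4 libraries only, 60 passed in MLL4 KO and 6659 in BAP1 KO. Against a fold change of 1.5, 135, 1014, 839 (difference), 2306 (control against WT) and 35 (same way) passed. With an estimated correlation 0 lists passed in either knockout, where camera had called 13 and 8.

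Leaving out each library gave 492 to 5300 genes for MLL4 KO, 1090 to 5024 for BAP1 KO, 679 to 4463 for the difference, 3280 to 7283 for control against WT and 119 to 1341 for the same way. The correlation of fold changes across genes was 0.064 with no filter on low counts, 0.153 with the stricter filter, 0.149 over genes past the threshold in either knockout, and 0.071 to 0.132 leaving out each library.

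KMT2D in MLL4 KO, at a log2 change near 0 throughout, turned sign to -0.002 with RLE factors and with DESeq2, -0.006 with limma-voom and the replicate block, and -0.007 with the crossed pairing, -0.112 without WT replicate 1 and -0.281 without MLL4 KO replicate 2, against 0.257 without MLL4 KO replicate 1. BAP1 in BAP1 KO was -0.051 without BAP1 KO replicate 1 and 0.181 without BAP1 KO replicate 2.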

Other observations

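The comparison of HOX clusters and of the fits on separate libraries was chosen after the data were seen. The HOX list did not pass as a whole in BAP1 KO (adjusted p = 0.0688), and its clusters differed. Of 11 measured HOXA genes 9 fell and none rose in BAP1 KO, with a median log2 change of -1.62. HOXA3 fell by 3.92 ± 0.53 and HOXA10 fell by 0.94 ± 0.13. Of 3 HOXD genes the ones that fell were HOXD3 and HOXD8. Of 9 HOXB genes 6 rose and none fell, with a median of 1.43, among them HOXB4 at 1.78 ± 0.21. In MLL4 KO the HOXB genes HOXB3, HOXB4, HOXB6 and HOXB9 also rose, with a cluster median of 0.98, while no HOXA or HOXD gene passed by edgeR. Of 8 HOXC genes 1 fell in BAP1 KO (median 0.08) and 1 rose in MLL4 KO (median -0.06), HOXC10 and HOXC11. On chromosome 7, a run of 41 neighbouring genes from 24796537 to 29990289 (hg38) that holds the HOXA cluster had a median of -0.96 in BAP1 KO, with 20 of its genes lower and 2 higher.

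The lists of subunits of the complexes studied did not pass in either knockout by camera, which tests for a shift in 1 direction. Of all tested genes, 19.1% passed in MLL4 KO and 22.4% in BAP1 KO. The change of the MLL3/MLL4 list differed between the knockouts by camera. Its median difference was -0.26 (adjusted p = 0.0427, or 0.557 with an estimated correlation). Of 18 genes of the MLL3/MLL4 and related complexes, 2 rose and 4 fell in MLL4 KO (adjusted p = 0.2), with the scaffold gene HCFC1 changing by -0.74 ± 0.14 and the demethylase gene KDM6A by 0.64 ± 0.17. KMT2A and SETD1B were those that rose in BAP1 KO. Of 14 genes around the BAP1 deubiquitinase, OGT and MBD6 rose and HCFC1 and BARD1 fell in MLL4 KO, while ASXL1, BARD1, BRCA1 and RBBP7 rose in BAP1 KO (adjusted p = 0.168). Polycomb genes went both ways: CBX7 rose by 1.17 ± 0.15 in MLL4 KO and by 0.98 ± 0.15 in BAP1 KO, BMI1 fell by 0.72 ± 0.17 and fell by 1.21 ± 0.17, and EZH2 changed by -0.42 ± 0.12 and by 0.66 ± 0.12. The intestinal keratin gene KRT20 rose in both, by 2.89 ± 0.41 and 3.43 ± 0.31, while HNF4A, a transcription factor of enterocytes, fell by 3.15 ± 0.65 in BAP1 KO. Of 17 enterocyte and colonocyte genes, 1 rose and none fell in MLL4 KO (camera, adjusted p = 0.0707). In BAP1 KO 1 rose and 6 fell (adjusted p = 0.0688). The change of this list differed between the knockouts by camera (adjusted p = 0.00154, or 0.374 with an estimated correlation). Markers of fibroblasts, endothelium and blood did not pass as a list in MLL4 KO (adjusted p = 0.212) or BAP1 KO (adjusted p = 0.37).

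When each knockout was fitted with its own 4 libraries alone, so that no library or spread was shared, 20 of the 46 genes higher in MLL4 KO were also higher in BAP1 KO, against 9.9 for independent lists. Of the 14 lower in MLL4 KO, 11 were also lower in BAP1 KO, against 2.9 (Fisher's exact test, one-sided, adjusted p = 0.00128 and 2.04e-05 over 4 directions, with genes not being independent replicates). The 20 hold both IGF2 and INS-IGF2, which share reads and are not separate evidence. The 11 included SLC1A3, MGLL, MEF2C, KRT15, IRAG1, ATP8B1, RNF141 and HAS3, which encodes a hyaluronan synthase.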
